A study of Mus musculus with 2 samples.

How the data were processed

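Liver RNA of Wip1 KO and WT mice, taken 24 h or 36 h after partial hepatectomy, was measured on 2 mouse oligonucleotide arrays, 1 per time. Per the labels, total RNA was isolated with Trizol and reverse-transcribed with dye-labelled nucleotides, Wip1 KO RNA carried Cy5 and WT RNA carried Cy3. The labels do not say how many animals gave the RNA of a channel or of which sex they were. With 1 array per time no replicate could be left out and no test or p-value was possible.

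Per the file headers, spots were quantified with LuxScan from scans at 635 nm and 532 nm, and the files hold raw foreground and local background intensities that were not normalised by the authors. The files also hold, as deposited, an unnormalised ratio of the 635 nm over the 532 nm signal of each spot and its log10 value, which were not used. A quality flag of each spot, whose meaning is not given per the file headers, was used in 1 added alternative only. A further table deposited by the authors holds a linear ratio of Wip1 KO over WT per feature, normalised by a method that is not stated and centred near 1 (medians 0.999 at 24 h and 1.00 at 36 h). It numbers its rows without probe names. Its rows were matched to the scanner files by order, which was checked by the correlation with the loess log ratios (0.971 and 0.974, against 0.0335 and 0.0591 when shifted by 1 row). It served as an alternative for the ratios and cannot give a time course within a genotype.

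Median foreground was corrected for background by normexp with an offset of 50, and log2 ratios were normalised by loess within each array with control spots at weight 0, in limma 3.58.1 under R 4.3.3. For the comparisons between times within a genotype, average brightness was made equal between arrays (Aquantile). A channel was above background when its foreground exceeded the local background by more than 2 background SDs. A gene counted as measured when both channels of the comparison were above background. Of 33696 spots, 1776 were controls and 31920 gene probes, of which 10479 were above background in both channels at 24 h and 9733 at 36 h. At 24 h 5 spots of Wip1 KO and 1 of WT were saturated, and at 36 h 15 and 0.

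Names in the files were brought to current mouse symbols with the gene table given. Of 19498 distinct names, 14166 matched a symbol, 3898 a synonym, 62 several genes and 1372 none. 7528 probes had no name and 23 had a name turned into a date by a spreadsheet program, and these were left out of comparisons by gene. Of 19439 genes 3663 had several probes, of which the probe with the highest mean brightness was used. No genome build is stated, so no positions are given. Counting and list comparisons used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

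The comparisons were Wip1 KO over WT at each time, the overlap and correlation of both, and 36 h over 24 h within WT and within Wip1 KO. A gene was called when at least 2-fold apart. The 37 gene lists, the threshold, the alternatives and the rule for naming genes were fixed before the data were examined. The lists cover p53 targets, G1/S, G2/M, DNA damage, ribosome biogenesis, mTOR, ribosomal proteins, hepatocyte products, bile acids, drug metabolism, fatty acid oxidation, fatty acid synthesis, cholesterol, glucose, urea and amino acids, acute phase, NF-kappa B, immediate early genes, interferon, macrophages, neutrophils, lymphocytes, endothelium, matrix, bile duct, erythroid cells, male-biased, female-biased and sex chromosome genes, circadian clock, heat shock, unfolded protein response, oxidative stress, growth factors, oxidative phosphorylation, pancreas, and muscle with fat. The median of a list was placed among those of 10000 random lists drawn from 20 brightness bins, and was called outside percentiles 2.5 to 97.5. Lists with fewer than 5 measured members got no percentile. If list members varied independently, 5% of lists would be called by chance, which is 1.7 of 34 at 24 h and 1.65 of 33 at 36 h. Members of a list can move together, so more lists could be called between any livers without an effect of genotype.

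Genes named are Ppm1d, and at each time the 5 highest and 5 lowest ratios among measured genes brighter than the median. From each list outside the range up to 4 members with the largest ratio in its direction are named, and from other lists up to 2 members at least 2-fold apart. For both times together the 5 highest and 5 lowest by the smaller ratio are named, and for each time course the 5 highest and 5 lowest bright genes. Not every gene that the rule names is printed. Values of these genes in the other comparisons are given where they illustrate a group. Y-linked genes, Cela2a, the list members shared between groups and the genes above background in 1 channel only were chosen after their values were seen.

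For a gene above background in 1 channel only, a lower bound of the fold was computed from the bright level and either the lowest signal above background in the dim channel or its own dim value, whichever was higher. Genes with another probe above background in the dim channel were left out, except Eif2s3y, whose bound at 36 h holds for its brighter probe alone, since its other probe was above background in WT. These bounds remain open to unequal dye uptake.

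The calling was tested on simulated data with known folds. Simulated noise had the SD of repeated control spots (0.115 at 24 h and 0.154 at 36 h) plus background noise. It held no spread between animals, labellings or probes of a gene, so the counts check the computation only. They give no rate of false calls for these arrays. At 24 h (8777 genes) 0 of 67 genes changed 1.5-fold were called, 62 of 64 at 3-fold and 59 of 59 at 6-fold, with 0 of 8568 unchanged genes. At 36 h (8505 genes) the numbers were 0 of 67, 62 of 65, 57 of 57 and 1 of 8296. Of 200 lists of randomly drawn genes without a change, 10 were called at 24 h and 8 at 36 h. A list with a planted shift reached percentile 100.0 at both times.

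Alternatives were no background subtraction, plain subtraction with values under 1 set to 1, a normexp offset of 16, median centring, print-tip loess, mean foreground, the deposited ratios, no filter on dim spots, a stricter filter (brightness above the median as well), the mean over probes, and thresholds of 1.5-fold and 3-fold. Time courses were also computed with quantile normalization of the 4 channels and with no normalization between arrays, and lists with unmatched random lists and with means. Added after seeing the data were only spots with a fitted position, omission of the sex-biased lists, and inclusion of genes above background in 1 channel at their bounds.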

Results

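Liver RNA of Wip1 knockout (KO) mice was set against liver RNA of wild-type (WT) mice on 2-colour oligonucleotide arrays, at 24 h and at 36 h after partial hepatectomy, an operation that removes part of the liver and makes the rest regrow. Wip1 is the protein of the gene Ppm1d, a phosphatase that removes phosphate from p53 and from other proteins of the DNA damage response. The mice were 3 months old. Each time had 1 array, with Wip1 KO RNA in the Cy5 channel and WT RNA in the Cy3 channel, and no array with the dyes exchanged. There were no replicates, so no difference could be set against a spread between animals, no test was possible, and the number of arrays limits the precision of every value. A gene that takes up the dyes unequally would stand apart on both arrays in the same direction.

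Of 31920 gene probes, 10608 (33.2%) were above background for Wip1 KO and 13224 (41.4%) for WT at 24 h. At 36 h the numbers were 9920 (31.1%) and 11754 (36.8%). The spread between repeated control spots within an array was small beside the 2-fold threshold used for calls. Spots of control genes repeated 48 times on the array had an SD of 0.115 log2 units at 24 h and 0.154 at 36 h. Probes for the same gene differed more, with an SD of 0.261 over 847 genes at 24 h and 0.257 over 808 genes at 36 h. Noise from labelling, dye or hybridization could not be measured, since there were no replicate arrays and none with the dyes exchanged. Group medians were compared with those of 10000 random gene lists of the same brightness, and a group was called higher or lower when its median lay outside the central range of these lists.

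Ppm1d, the gene removed in the KO, was below background in both channels at both times on its only probe. The arrays therefore give no ratio for it and do not show which channel holds the KO RNA, which rests on the labels.

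The first comparison asks how Wip1 KO liver differs from WT at 24 h. Genes of connective tissue, bile duct cells and mitosis were higher in Wip1 KO, and interferon-induced, macrophage and female-biased genes were lower. Col1a2, a chain of type I collagen, was 4.45-fold higher, the bile duct and progenitor marker Prom1 4.04-fold and the proliferation marker Mki67 2.99-fold. Igfbp1, a secreted binding protein induced early in liver regeneration, was 4.19-fold higher. Sult3a2, a sulfotransferase, was 16.2-fold lower.

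Among 8018 genes measured in both channels at 24 h, 122 were at least 2-fold higher and 62 at least 2-fold lower in Wip1 KO, 2.29% of the total. The split between the directions depended on the scaling, with 84 higher and 92 lower under median centring in place of loess. Besides Col1a2 and Igfbp1, the highest bright genes were the NKG2D ligand Raet1d (log2 ratio 2.23), the thyroxine carrier Serpina7 (2.02) and the corticosteroid carrier Serpina6 (1.82). Besides Sult3a2, the lowest bright genes included the sulfotransferases Sult1e1 (-2.45) and Sult2a2 (-2.20) and the cytochrome P450 gene Cyp2c39 (-1.84).

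Connective tissue and duct genes set Wip1 KO liver furthest above WT at 24 h. All 18 measured genes of stellate cells and extracellular matrix were above 0, 8 of them at least 2-fold, with a median log2 ratio of 0.96 against a random range of -0.17 to 0.20. Besides Col1a2, Col5a1 was 3.20-fold, the smooth muscle actin gene Acta2 3.07-fold and the matrix protein gene Sparc 2.95-fold higher. Of 8 bile duct markers 7 were above 0 (median 0.80, or 0.44 without the filter on dim spots), led by Prom1, Spp1 (3.28-fold), Cldn7 (1.94-fold) and Krt19 (1.78-fold). Endothelial markers as a group stayed within the random range (median 0.02), although the scavenger receptor gene Stab1 was 2.25-fold higher. Erythroid markers were higher (4 of 5 above 0, median 0.52), with beta-globin Hbb-b1 2.39-fold and alpha-globin Hba-a1 1.90-fold higher, but without the filter on dim spots the median was -0.0009.

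Mitotic genes were higher in Wip1 KO at 24 h while genes of DNA replication were not apart. Of 26 measured G2/M genes 24 were above 0 and 4 at least 2-fold higher, namely Mki67, Ccnb2 (2.86-fold), Top2a (2.33-fold) and Ttk (2.02-fold). Their median was 0.61, above the random range of -0.11 to 0.19. The mitotic genes Cdc20 and Kif2c were above background in Wip1 KO only, at least 2.36-fold and 2.21-fold higher, while 4 other G2/M genes were above background in WT only, none at least 2-fold lower in Wip1 KO. The 44 genes of G1/S transition and DNA replication had a median of 0.01, with none 2-fold apart.

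Targets of p53, the transcription factor that Wip1 restrains, were higher in Wip1 KO at 24 h. The median of 19 targets was 0.31 (percentile 99.9 of the random lists) and 14 were above 0. Gadd45a was 2.22-fold, Phlda3 2.02-fold, the cell cycle inhibitor Cdkn1a 1.59-fold and Trp53inp1 1.57-fold higher. With a stricter filter on dim spots, which left 8 targets, the median was 0.10 and within the random range. The 22 genes of DNA damage response and repair were evenly divided, 11 above and 11 below 0.

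Immediate early genes, which answer growth signals within minutes, had a median of 0.51 over 14 genes at 24 h, with 11 above 0. The median was 0.27 without the filter on dim spots and 0.83 from spots with a fitted position. Egr1 was 3.66-fold, Ier3 2.20-fold, Myc 2.07-fold and Dusp6 1.80-fold higher. Growth factors and regeneration signals were within the random range (11 genes, median 0.20), with Hbegf 2.20-fold higher. In the mTOR pathway (22 genes, median -0.06, within range) the mTOR inhibitor Ddit4 was 2.13-fold and the insulin receptor substrate Irs2 2.01-fold lower. Ribosome biogenesis was within range (20 genes, median -0.13) but was called lower under 2 alternatives, at -0.14 without the filter on dim spots and -0.17 with genes above background in 1 channel at their bounds. Cytosolic ribosomal proteins were within range (24 genes, median -0.07), although the 48 control spots of the ribosomal protein gene Rpl5 had a mean of 0.45.

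Hepatocyte metabolism was shifted by pathway at 24 h. Genes of the urea cycle and amino acid catabolism were higher in Wip1 KO (21 of 26 above 0, median 0.37), with Glul, the glutamine synthetase of hepatocytes around the central vein, 3.71-fold higher, Agxt 1.87-fold and Gls2 1.83-fold. Gluconeogenesis and glucose handling was higher (14 of 19, median 0.33, or 0.20 in the deposited ratios), led by Igfbp1 and by Pfkfb3 (2.27-fold, or a log2 ratio of 0.49 as the mean over its probes), with Gys2 1.87-fold. Hepatocyte secreted proteins and transcription factors had a median of 0.28, 19 of 24 above 0, with Ahsg 1.67-fold, Trf 1.66-fold and Apoh 1.60-fold higher, and were within the random range at 0.25 with the stricter filter on dim spots. Fatty acid and triglyceride synthesis had a median of 0.21 over 20 genes, which was -0.040 without the filter on dim spots. In that group Fasn was 2.34-fold, Elovl6 2.19-fold and Acaca 2.38-fold higher, the last with a log2 ratio of 0.32 as the mean over its probes.

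Lipid burning and sterol genes were lower in Wip1 KO at 24 h. Fatty acid oxidation genes and targets of the nuclear receptor PPAR alpha had a median of -0.20, 16 of 24 below 0, with Cyp4a10 2.19-fold and Crat 1.71-fold lower. As the mean over probes this median was -0.06 and within the random range. Of 23 cholesterol synthesis genes 20 were below 0 (median -0.22, or -0.34 under median centring), among them Cyp51 (1.58-fold), Fdft1 (1.52-fold) and Msmo1 (1.49-fold). Bile acid synthesis and transport (17 genes, median 0.06) and drug metabolism (25 genes, median 0.14) were within range, the latter called higher at 0.11 under median centring. Single members stood apart, with the bile acid sensor gene Nr0b2 2.81-fold and Cyp2c55 5.04-fold higher and Cyp2c39 3.57-fold lower.

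Genes of the interferon response were lower in Wip1 KO at 24 h, 17 of 19 below 0 and 5 at least 2-fold, with a median of -0.46 against a random range of -0.18 to 0.19. Usp18 was 3.58-fold, the transcription factor Irf7 2.91-fold, Oas1a 2.74-fold and Irgm1 2.41-fold lower. Markers of macrophages and Kupffer cells, the resident macrophages of the liver, were lower (15 of 21 below 0, median -0.27). Among these the Kupffer cell lectin Clec4f was 2.29-fold, Fcgr1 2.05-fold and Cd5l 1.93-fold lower. Acute phase genes had a median of -0.12, with 17 of 30 below 0, Saa4 2.69-fold and Crp 1.80-fold lower. That call was lost under 4 alternatives, with a median of -0.02 under print-tip loess.

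NF-kappa B targets had a median of 0.21 over 15 genes at 24 h, within the random range, but were called higher under 4 alternatives, such as the stricter filter on dim spots (0.42) and plain background subtraction (0.37). Among them Il1b was 2.16-fold higher and Vcam1 2.82-fold higher on its brightest probe, while its probes differed in direction. Lymphocyte markers (8 genes) had a median of 0.26, within range, and were called higher at 0.39 as the mean over probes. Neutrophil markers (7 genes, median 0.06, mean -0.25, within range) were called higher at 0.22 without the filter on dim spots and lower at -0.36 from spots with a fitted position, so their direction stays open. Prtn3 was 3.45-fold lower.

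Heat shock proteins were lower in Wip1 KO at 24 h, 12 of 14 below 0, with a median of -0.38. Hspb8 was 1.61-fold, the co-chaperone Stip1 1.57-fold and Hsp90aa1 1.53-fold lower. The unfolded protein and amino acid response was within range (17 genes, median -0.13), with Sdf2l1 2.02-fold lower, but was called lower under 7 alternatives, down to -0.26 under median centring. The oxidative stress response was within range too (19 genes, median 0.13), but was called higher under 4, from 0.23 with print-tip loess to 0.45 with the stricter filter on dim spots. Its glutathione transferases Gsta2 (2.25-fold) and Gsta4 (2.21-fold) were higher. Circadian clock genes (13 genes, median -0.03) and oxidative phosphorylation (30 genes, median 0.04) were not apart.

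Female-biased liver genes, whose expression depends on the female pattern of growth hormone, had a median of -0.83 at 24 h, or -0.50 without the filter on dim spots, with 5 of 11 at least 2-fold lower and 1 at least 2-fold higher. Besides Sult2a2, A1bg was 4.15-fold and Cyp3a41a 2.26-fold lower. Male-biased genes had a median of 0.30, at the upper edge of the random range (6 genes, percentile 97.3), and were called higher at 0.20 under median centring and at 0.30 as the mean over probes. The Y-linked Ddx3y and Usp9y were measured at 24 h, with log2 ratios of 0.086 and 0.037. Eif2s3y, also on the Y chromosome, has a pair of probes, of which the brighter was below background in both channels at 24 h and the other gave a log2 ratio of 0.18. Xist is not on the array.

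**Figure D1:**
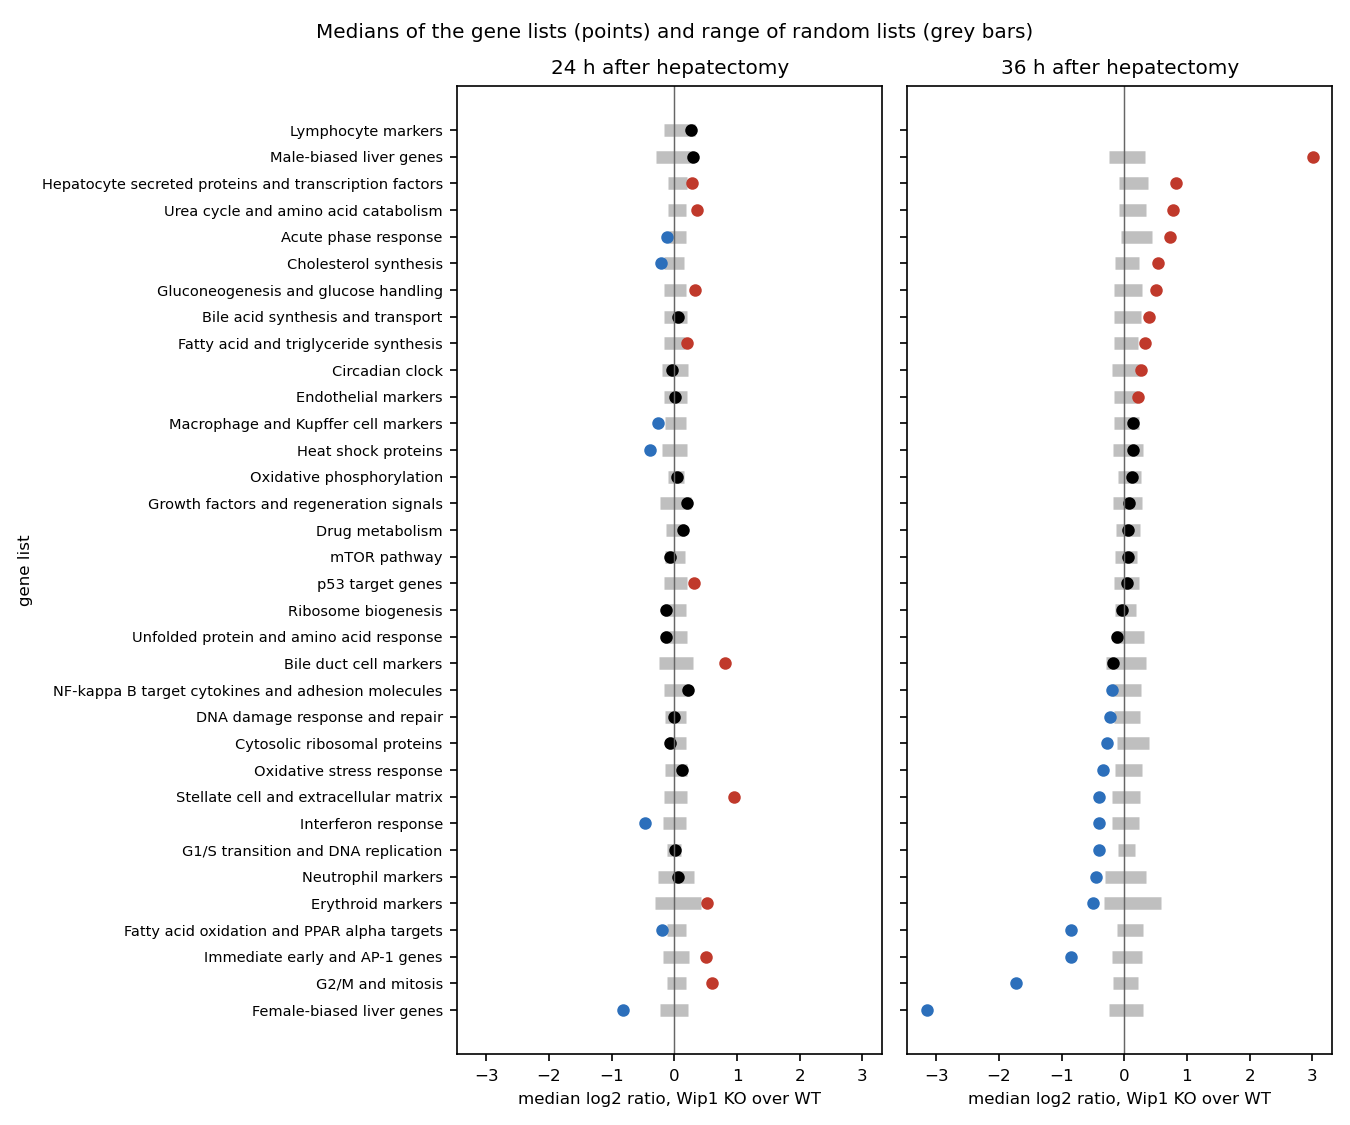
Median log2 ratio of Wip1 KO over WT of each fixed gene list with at least 5 measured genes, at 24 h and 36 h (points), with the central range of the medians of 10000 brightness-matched random lists as grey bars. At 24 h 17 of 34 lists lay outside their range and at 36 h 23 of 33, with G2/M genes at 0.61 and -1.72 and female-biased genes at -0.83 and -3.15.

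The same question was asked at 36 h, a later point of regrowth. Mitotic genes were lower in Wip1 KO at this time, as were genes of fatty acid oxidation, while genes of mature hepatocytes, amino acid catabolism and the acute phase were higher. The mitotic regulator Cdc20 was 6.18-fold lower and cyclin B2, Ccnb2, 5.26-fold lower. Cps1, the first enzyme of the urea cycle, was 4.42-fold higher. The widest differences were in genes that male and female liver express differently: A1bg was 84.6-fold lower and Elovl3 52.2-fold higher in Wip1 KO.

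In all, 198 of 7460 genes were at least 2-fold higher and 154 at least 2-fold lower in Wip1 KO at 36 h, 4.72% of those measured. The split was 241 and 126 under median centring, 218 and 236 without the filter on dim spots, and 208 and 227 with genes above background in 1 channel at their bounds, so which direction prevailed depended on the filter. After A1bg the lowest bright genes were Sult3a1 (log2 ratio -5.03), Sult3a2 (-5.01) and Sult2a2 (-4.46). The highest after Elovl3 were the oxysterol hydroxylase gene Cyp7b1 (4.37), Cyp4a12b (4.05), the steroid dehydrogenase gene Hsd3b5 (4.05) and the coenzyme A hydrolase gene Nudt7 (3.01).

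Sex-biased liver genes separated the channels of the 36 h array. Of 9 male-biased genes all were above 0 and 8 at least 2-fold higher in Wip1 KO (median 3.01), among them Elovl3, Cyp4a12b, Hsd3b5 and the complement gene C6 (9.55-fold). All 11 female-biased genes were below 0 and 10 at least 2-fold lower (median -3.15), led by A1bg, Sult3a1 and Sult2a2. The Y-linked genes Ddx3y and Kdm5d had log2 ratios of 1.40 and 0.80 and were above background in both channels. The Y-linked Usp9y was above background in WT only, with a log2 ratio of 0.22. The brighter Eif2s3y probe was above background in Wip1 KO only, at least 14.3-fold higher than WT on that probe. The dimmer probe for the same gene was above background in WT only, with a log2 ratio of -0.086. Every other group at 36 h was measured on this same pair of RNAs.

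**Figure D2:**
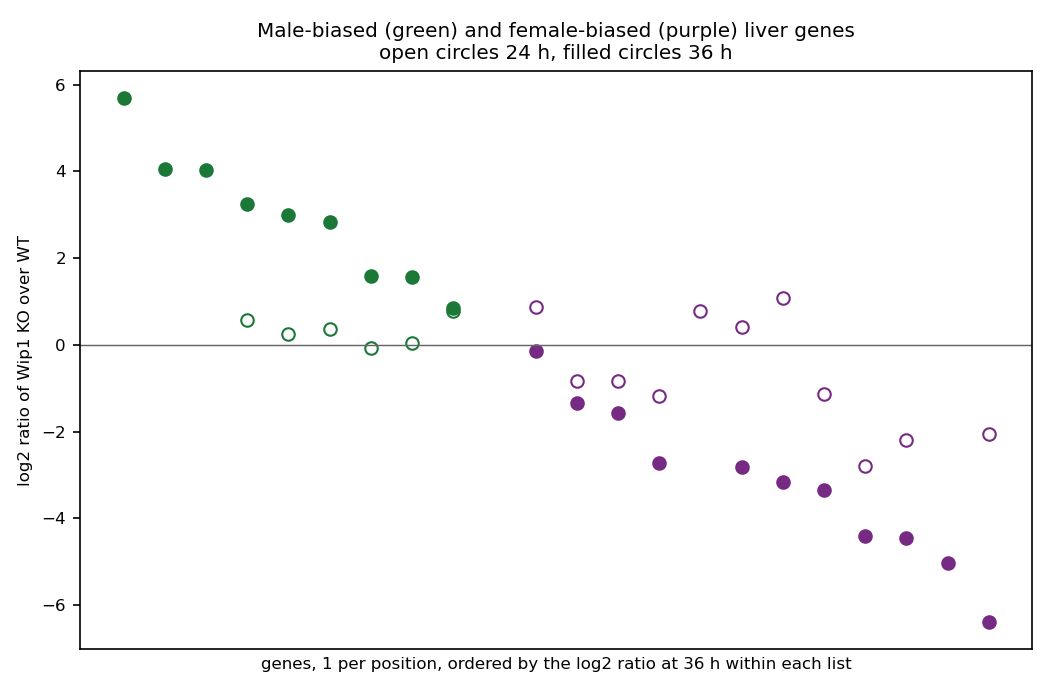
Log2 ratio of Wip1 KO over WT of each measured male-biased (green) and female-biased (purple) liver gene, at 24 h (open circles) and 36 h (filled circles). The medians were 0.30 and -0.83 at 24 h and 3.01 and -3.15 at 36 h.

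Cell cycle genes were lower in Wip1 KO at 36 h, most of all those of mitosis. All 16 measured G2/M genes were below 0, 13 at least 2-fold, with a median of -1.72 against a random range of -0.18 to 0.22. Cenpa, the histone of the centromere, was 5.64-fold and the kinase Aurka 4.93-fold lower, besides Cdc20 and Ccnb2. A further 20 G2/M genes were above background in WT only, 10 of them at least 2-fold lower in Wip1 KO, such as Ccnb1 (at least 4.79-fold) and Kif2c (at least 4.05-fold). With these genes at their bounds the median was -1.31.

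Genes of G1/S transition and DNA replication were lower by less at 36 h, 30 of 34 below 0 with a median of -0.41. The licensing factor Cdt1 was 4.31-fold, cyclin D1 (Ccnd1) 3.70-fold and Tyms 2.07-fold lower. DNA damage response and repair genes were lower as well (12 of 15 below 0, median -0.23), with Trp53, the p53 gene, 1.66-fold and Ung 1.61-fold lower. Targets of p53 were within the random range (17 genes, median 0.05), Cdkn1a at 0.04 and Gadd45a at 0.02. Cytosolic ribosomal proteins had a median of -0.27, or -0.14 under median centring, 20 of 23 below 0, none by 2-fold, among them Rplp1 (1.40-fold) and Rpl12 (1.39-fold). Ribosome biogenesis (20 genes, median -0.04) and the mTOR pathway (22 genes, median 0.06) were within range.

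Genes of mature hepatocytes were higher in Wip1 KO at 36 h. Hepatocyte secreted proteins and transcription factors had a median of 0.83, 24 of 25 above 0, with Ahsg 2.37-fold and the transcription factor Onecut1 2.31-fold higher. Urea cycle and amino acid catabolism genes were above 0 in 25 of 26 cases, 12 at least 2-fold (median 0.78), with Cps1 ahead of Tdo2 (4.24-fold) and Hal (2.76-fold). Gluconeogenesis and glucose handling had a median of 0.51 over 16 genes, with Sds 4.02-fold and Fbp1 3.54-fold higher and Igfbp1 3.88-fold lower. Bile acid synthesis and transport was higher (13 of 17, median 0.40, or 0.65 as the mean of the members), with Cyp7b1, which male liver makes more of, 20.7-fold and Cyp8b1 9.83-fold higher.

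Lipid genes were opposed by pathway at 36 h. Cholesterol synthesis was higher in Wip1 KO, 17 of 18 above 0 (median 0.53), with Idi1 3.70-fold, Fdps 2.15-fold and Sc5d 2.09-fold. Fatty acid and triglyceride synthesis had a median of 0.33 (13 of 19 above 0), with Acly 2.72-fold and Scd1 1.97-fold higher, but 0.14 and within the random range without the filter on dim spots. Fatty acid oxidation and PPAR alpha targets were below 0 in 22 of 24 cases and at least 2-fold lower in 10, with a median of -0.85. Cyp4a14 was 16.2-fold, Cyp4a10 10.2-fold, the PPAR alpha target Angptl4 4.19-fold and Vnn1 3.76-fold lower, and Cyp4a10 also stands in the female-biased list.

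Drug metabolism genes went both ways at 36 h (25 genes, median 0.06 and mean -0.07, within range), Cyp2b9 8.89-fold lower and Gstp1 2.96-fold higher, both of which are sex-biased. The oxidative stress response was lower (14 of 19 below 0, median -0.33, or -0.18 under median centring), with the glutathione transferase Gsta1 2.72-fold, Gsta2 1.85-fold and Nqo1 1.79-fold lower. Oxidative phosphorylation (30 genes, median 0.12) was within range.

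Acute phase genes, which the liver secretes in inflammation, were higher in Wip1 KO at 36 h, 27 of 29 above 0 and 9 at least 2-fold (median 0.73). Saa4 was 5.46-fold, the protease inhibitor A2m 5.19-fold, Steap4 3.23-fold and Hpx 3.13-fold higher. Interferon genes were lower (10 of 15 below 0, median -0.40), with Irf7 2.56-fold and Rsad2 2.31-fold lower. With a stricter filter on dim spots their median was 0.15. Neutrophil markers were below 0 in all 6 cases (median -0.45, or -0.28 without the filter on dim spots), with Retnlg 1.78-fold and Chil3 2.76-fold lower, the latter with a log2 ratio of -0.72 as the mean over its probes. NF-kappa B targets had a median of -0.20 over 12 genes, just outside the random range, with Ccl2 2.14-fold lower, and were within it under 3 alternatives, such as the stricter filter on dim spots (-0.18). Macrophage markers (18 genes, median 0.15) were within range.

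Immediate early genes were lower in Wip1 KO at 36 h, 8 of 10 below 0 (median -0.85, or -0.43 without the filter on dim spots), with Ier3 3.31-fold, Gadd45b 2.69-fold and Ccn1 2.44-fold lower. Matrix genes were below 0 in 13 of 14 cases (median -0.40), Tagln 3.57-fold and Acta2 2.26-fold lower. With a stricter filter on dim spots the matrix median was -0.14 and within the random range. Erythroid markers had a median of -0.50 over 5 genes, with Car2 2.73-fold lower and Alas2 3.38-fold higher, and were within range under print-tip loess (-0.31) and as the mean of the members (-0.14). Bile duct markers (6 genes, median -0.18) were within range, with Krt23 2.35-fold higher. A further 6 were above background in WT only, 1 of them, Prom1, at least 2-fold lower in Wip1 KO.

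Endothelial markers (18 genes, median 0.22, Stab2 2.36-fold higher) and circadian clock genes (12 genes, median 0.27, Cry1 2.23-fold higher) lay just above their random ranges at 36 h, and several alternatives brought them inside. Heat shock proteins were within range (14 genes, median 0.13), with Dnajb1 2.06-fold lower. The unfolded protein and amino acid response was within range (15 genes, median -0.12), with Creld2 2.87-fold lower and Asns 2.72-fold higher, but was called lower at -0.22 without the filter on dim spots. Growth factors and regeneration signals (12 genes, median 0.08) included Egfr, 2.57-fold higher. Lymphocyte markers had 3 measured genes, too few for a percentile, with Cd3g 2.48-fold higher. Of the pancreatic acinar markers 1 gene, Cela2a, was measured at both times (log2 ratios 0.58 and 0.31), and no skeletal muscle or adipose marker was above background in both channels at either time.

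Next, the times were set side by side to find genes that differ between the genotypes throughout. Over the 7025 genes measured at both times, 13 were at least 2-fold higher and 15 at least 2-fold lower in Wip1 KO at both, where independent draws would give 2.19 and 1.23. Among the lowest were Sult3a2 (log2 ratios -4.02 and -5.01), Sult1e1 (-2.45 and -2.53), the DNA fragmentation factor Dffa (-2.26 and -2.47) and Sult2a2 (-2.20 and -4.46). Irf7 was lower at both times too. The highest were A2m (1.95 and 2.38), Serpina6 (1.82 and 1.47), Mug4-ps (1.45 and 2.73), Cyp1a2 (1.77 and 1.39) and Fam25c (1.41 and 1.37). These genes have the same dye assignment on both arrays, so unequal dye uptake is not excluded for them.

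Across genes, the ratios at 24 h and at 36 h were barely related (Pearson r 0.065, Spearman rho 0.0553 over 7025 genes, which are not independent replicates). At least 2-fold in opposite directions were 19 genes, of which 16 were higher at 24 h and lower at 36 h (1.85 expected from independent draws) and 3 lower and then higher (1.45 expected). The 16 include the mitotic genes Ccnb2, Mki67 and Ttk, the smooth muscle genes Acta2 and Tagln, the immediate early gene Ier3, and Igfbp1. Saa4 is among the 3. Of 33 lists, 23 had a difference between the times outside the random range. G2/M genes differed by -2.29, immediate early genes by -1.59, bile duct markers by -1.37, matrix genes by -1.20 and acute phase genes by 1.04. Without the filter on dim spots the immediate early difference was -0.63 and the bile duct difference -0.42.

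**Figure D3:**
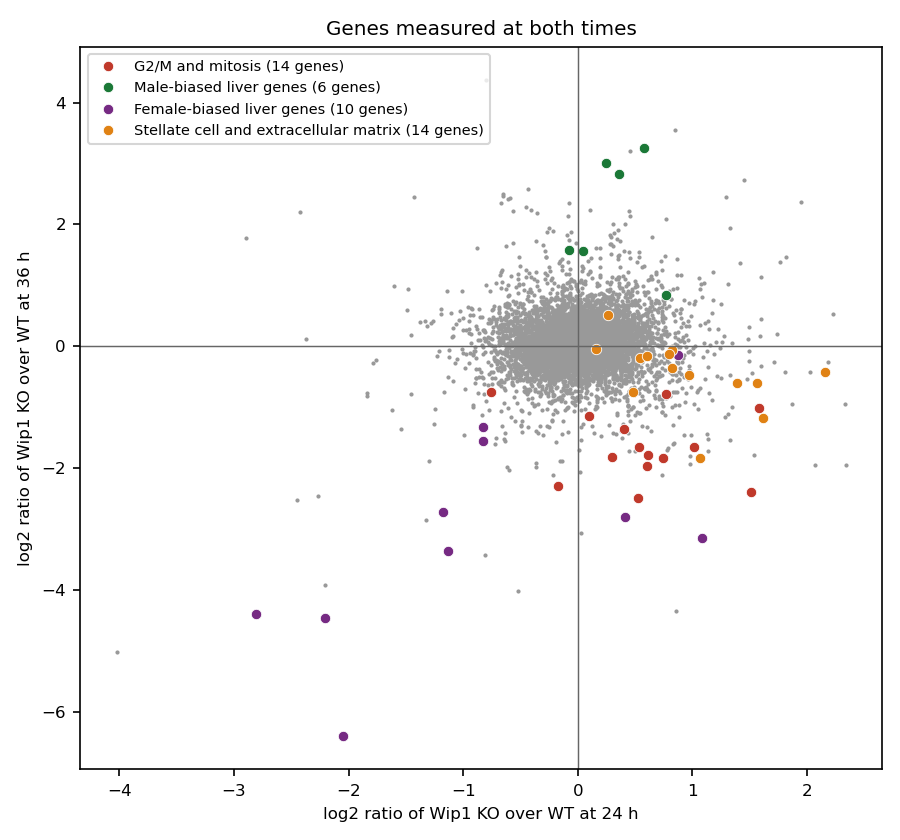
Log2 ratio of Wip1 KO over WT at 24 h against 36 h for the 7025 genes measured at both times, with G2/M, male-biased, female-biased and matrix genes coloured. G2/M genes lie mostly at positive values at 24 h and negative values at 36 h (medians over all measured members 0.61 and -1.72), and matrix genes shift from 0.96 to -0.40.

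The last comparisons follow each genotype from 24 h to 36 h across the arrays, to see which genotype moved. In WT, mitotic genes were higher at 36 h than at 24 h and cholesterol synthesis genes lower. In Wip1 KO, mitotic genes were lower at 36 h, and acute phase and macrophage genes higher. Ccnb2 was 6.39-fold higher at 36 h in WT and 2.35-fold lower in Wip1 KO. Array and time cannot be separated in these comparisons, because each time is a single array. The labels do not give the sex of the animals, so a difference of sex between the times within a genotype is not excluded either. In Wip1 KO the brighter probe of the Y-linked Eif2s3y was above background at 36 h but not at 24 h.

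Between the times, 118 of 8587 genes were at least 2-fold higher and 133 lower at 36 h in WT, and 183 of 7113 higher and 256 lower in Wip1 KO. Under median centring the split was 93 and 166 in WT and 263 and 208 in Wip1 KO. The bright genes with the largest increase in WT were A1bg (log2 ratio of 36 h over 24 h 4.51), the aldo-keto reductase Akr1b7 (3.42), Mtss1 (2.88, or 0.93 as the mean over its probes), Ccnb2 (2.68) and Pcyt1a (2.46). The largest decreases in WT were those of Cyp2c39 (-4.69), Uqcrfs1 (-3.78, or -0.65 from mean foreground), Orm3 (-2.75), Fshb (-2.72) and Mup10 (-1.82). In Wip1 KO the largest increases were those of Cyp7b1 (4.47), Abhd14b (4.15), Tff3 (2.97), Mtss1 (2.63) and C6 (2.49). The largest decreases in Wip1 KO were those of Cyp2c39 (-3.66), Cyp4a14 (-3.10), the DNA methylation factor Uhrf1 (-3.09), Cyp2b9 (-2.95) and Acta2 (-2.83).

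The genotypes moved apart in mitotic genes. In WT 27 of 29 G2/M genes were higher at 36 h, 13 at least 2-fold, with a median of 0.92, Ccnb2 and Cenpa (3.48-fold) among them. In Wip1 KO all 15 measured G2/M genes were lower at 36 h, 11 at least 2-fold, with a median of -1.23, among them Ttk (3.42-fold) and Mki67 (3.20-fold). Genes of G1/S transition and DNA replication were lower at 36 h in both genotypes, 38 of 42 in WT (median -0.78) and 34 of 35 in Wip1 KO (median -1.10), with Fen1 1.77-fold lower in WT and 3.23-fold in Wip1 KO.

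**Figure D4:**
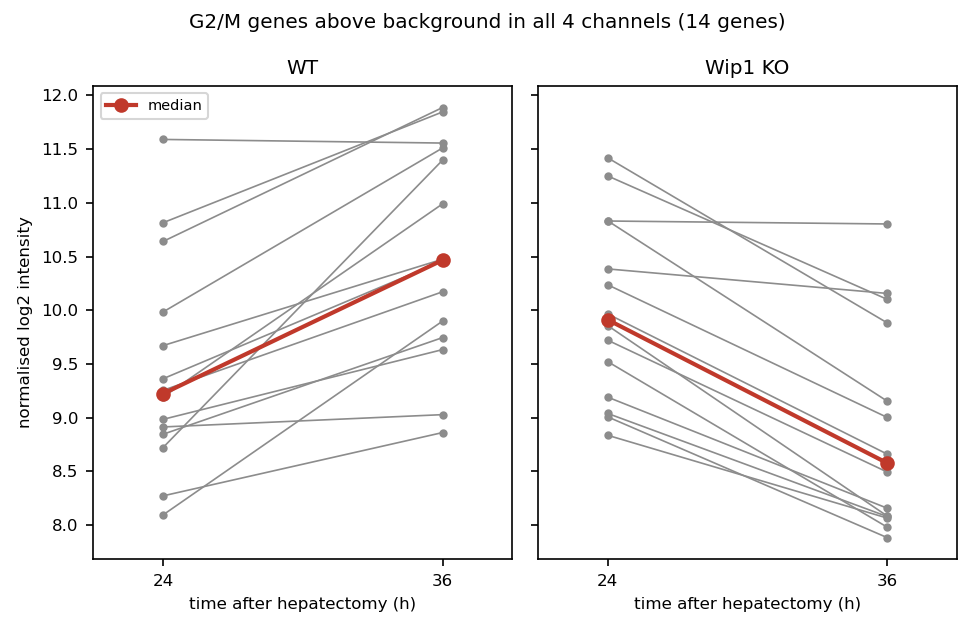
Normalised log2 intensity of the 14 G2/M genes above background in all 4 channels, at 24 h and 36 h, in WT and in Wip1 KO, with 1 line per gene and the median in red. The median went from 9.22 to 10.47 in WT and from 9.91 to 8.58 in Wip1 KO.

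Matrix and bile duct genes moved in Wip1 KO. Of 14 matrix genes 13 were lower at 36 h in Wip1 KO (median -0.99), Col1a2 5.65-fold and Sparc 3.30-fold, while in WT the median was 0.22, and -0.037 with a stricter filter on dim spots. All 5 measured bile duct markers were lower at 36 h in Wip1 KO (median -1.38, or -0.50 without the filter on dim spots), Spp1 4.03-fold. Krt23 was above background at 36 h only, at least 3.65-fold higher, while 3 other markers were above background at 24 h only, 2 of them at least 2-fold lower at 36 h. Macrophage markers were higher at 36 h in Wip1 KO (15 of 19, median 0.64, or 0.30 with either the stricter filter or no filter on dim spots), Clec4f 2.84-fold, and within the random range in WT (median -0.04). Immediate early genes had medians of 0.29 in WT, which was 0.14 and within range with no normalization between arrays, and -0.54 in Wip1 KO, with Egr1 5.14-fold lower in Wip1 KO.

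Cholesterol synthesis genes were lower at 36 h in 20 of 21 cases in WT, 13 at least 2-fold (median -1.06), with Idi1 3.39-fold and Cyp51 3.13-fold lower. In Wip1 KO their median was -0.31, or -0.06 and within range as the mean over probes. Fatty acid oxidation genes were higher at 36 h in WT (22 of 25, median 0.40) and within range in Wip1 KO (median -0.12), where they were called lower under 5 alternatives, from -0.13 as the mean over probes to -0.40 as the mean of the members. Acute phase genes went opposite ways, with medians of -0.47 in WT and 0.48 in Wip1 KO, and Saa4 2.83-fold lower in WT and 5.18-fold higher in Wip1 KO. Female-biased genes did so as well, with medians of 0.70 in WT (13 of 14 above 0, or 1.08 as the mean of the members) and -1.13 in Wip1 KO (9 of 10 below 0). Male-biased genes had medians of -0.43 in WT, which was 0.076 without the filter on dim spots and -0.18 within range as the mean over probes, and 1.43 in Wip1 KO.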

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

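Of the tests below, those of X-linked genes and of the intensity-dependent normalization were planned before their results were seen, and the others were chosen only after the result was seen.

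Several groups stood apart in opposite directions at 24 h and 36 h. None of these differences between the times was tested, because each time has 1 array. The median difference of the log2 ratios, 36 h minus 24 h, was -2.29 for G2/M genes, -1.59 for immediate early genes, -1.20 for matrix genes and -1.15 for erythroid markers, all higher in Wip1 KO at 24 h and lower at 36 h. Cholesterol synthesis (0.84) and acute phase genes (1.04) went from lower to higher, but the 24 h call of the acute phase genes was lost under 4 alternatives, with -0.02 under print-tip loess. The 36 h call was lost for matrix genes with the stricter filter on dim spots (-0.14) and for erythroid markers as the mean of the members (-0.14). Without the filter on dim spots the erythroid difference was -0.11 and within the random range, and the immediate early difference was -0.63.

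Among named genes at least 2-fold apart at both times in opposite directions, the differences were likewise not tested. The mitotic genes Ccnb2, Ttk and Mki67 differed by -3.91, -2.67 and -2.60, and the smooth muscle genes Tagln and Acta2 by -2.90 and -2.79. Igfbp1 differed by -4.02, Ier3 by -2.86, the female-biased Cyp2b9 by -4.23 and Gsta1 by -2.57. Saa4 went the other way, by 3.88.

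In the 36 h array, male-biased genes were higher and female-biased genes lower in Wip1 KO. Unequal dye uptake is excluded as the whole cause, because the female-biased list moved by -1.91 between arrays with the same dyes. RNA from a Y chromosome carrier in the Wip1 KO channel alone may give the log2 ratio of at least 3.83 of the brighter Eif2s3y probe, but stays open, because 3 of 4 other Y-linked genes (Ddx3y, Kdm5d and Usp9y) and the other Eif2s3y probe were above background in WT, where X homologues might bind the probes. Livers of different sex cannot be told apart from an effect of the genotype on sex-biased genes, since the X-linked genes that escape inactivation had a median of 0.018 over 3 genes, neither below -0.1 as predicted nor above the spot SD, and their Y homologues may bind the same probes. At 24 h female-biased genes were also lower in Wip1 KO (-0.83) without that Eif2s3y signal. Its absence does not settle the sex at 24 h, since the Y-linked probes did not answer alike at 36 h. There Ddx3y (1.40) and Kdm5d (0.80) were higher in Wip1 KO. Usp9y (0.22) and the dimmer Eif2s3y probe (-0.086) were close to background and differed little between the channels.

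Mitotic genes were higher in Wip1 KO at 24 h and lower at 36 h. A dye effect is excluded as the whole cause by the change of -2.29 between arrays with the same dyes. It could still give the value at either time, since an equal dye effect on both arrays cancels in this change. The intensity-dependent normalization is excluded by the 24 h median, which was at least 0.49 under median centring and in the deposited ratios. A difference of sex cannot be told apart from one of genotype for the 36 h part (-1.72), because 1 array compares these RNAs. It stays open for the 24 h part too, where Ddx3y stood at 0.086 and the brighter Eif2s3y probe was below background in both channels. These values do not settle the sex, since the Y-linked probes did not answer alike at 36 h. A mitotic wave shifted in time in Wip1 KO stays open as a biological explanation and was not tested.

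Matrix and bile duct genes were higher in Wip1 KO at 24 h. Fewer hepatocytes with an equal rise of all other cells would not cover the macrophage markers, which were lower (-0.27). Hepatocyte secreted proteins and transcription factors, which that explanation would lower, had medians from 0.19 to 0.28 under the alternatives. Endothelial markers, which it would raise, were within the random range. Macrophage and hepatocyte genes can change on their own and 1 array was measured, so a lower share of hepatocytes in the Wip1 KO sample is not excluded. Dye uptake alone would not raise the matrix genes at 24 h and lower them at 36 h (median -0.40). With the stricter filter on dim spots the 36 h median was -0.14 and within the random range. Bile duct markers were within range at 36 h, so that time does not exclude dye uptake for them. Dye uptake could still give part of the 24 h values, since an equal dye effect on both arrays leaves their difference unchanged. More tissue from portal tracts or from the wound edge could give the same values, with bile duct markers at 0.80. It cannot be told apart from a change of these cells in Wip1 KO, since no marker separates sampling from such a change.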

How the results depend on the processing

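The alternatives that left out the sex-biased lists, kept only spots with a fitted position, or added genes above background in 1 channel at their bounds were chosen only after the result was seen, and all others were planned.

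Of 67 list results at 24 h and 36 h, within or outside the random range, 45 were kept under every alternative that gave a value. Of 100 such results for the time courses and the difference between times, 65 were kept. Of 219 values of named genes, 180 kept their side of the 2-fold threshold under every alternative that gave a value, and none changed direction. The G2/M, female-biased and bile duct calls at 24 h and the G2/M, male-biased and female-biased calls at 36 h were kept wherever the list had enough members, with G2/M medians from 0.49 to 0.79 at 24 h and from -2.01 to -1.23 at 36 h. Of the lists outside their random range, those whose median changed sign were, without the filter on dim spots, fatty acid and triglyceride synthesis (-0.040) and erythroid markers (-0.0009) at 24 h and male-biased genes in WT over time (0.076). With the stricter filter on dim spots they were the interferon response at 36 h (0.15) and, in WT over time, neutrophil markers (-0.043) and matrix genes (-0.037). Medians near 0 of lists within their range crossed 0 as well, such as that of neutrophil markers at 24 h, 0.22 without the filter and -0.36 from spots with a fitted position. Without the filter 30 of 102 medians outside their range shrank by more than 1.5 times. The cause was not tested.

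The number of genes at least 2-fold apart depended on the background correction. At 24 h it was 300 with no background subtraction and 321 with plain subtraction, against 184. It was 309 in the deposited ratios, whose normalization was not stated, so this difference is not ascribed to the background correction. In WT over time it was 404 with no background subtraction and 466 with plain subtraction, against 251, and in Wip1 KO 659 with plain subtraction, against 439. The cause was not tested. Without the filter on dim spots more genes enter by construction, and 809 were apart in Wip1 KO over time. The stricter filter admits fewer genes by construction and gave 97 at 24 h, 122 in WT over time and 222 in Wip1 KO over time, and 14 of 27 lists outside the random range at 36 h.

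By construction a 1.5-fold threshold gave more genes, 878 at 24 h, 1083 at 36 h, 130 in the same direction at both times, 925 in WT over time and 1436 in Wip1 KO over time. A 3-fold threshold gave 42, 116, 8, 62 and 97. Leaving out the sex-biased lists gave 178 genes at 24 h, 334 at 36 h and 23 at both times. The correlation between times lay between 0.0142 without the filter on dim spots and 0.127 with the stricter filter.

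Ppm1d was below background in both channels, so its ratios do not measure the gene. At 24 h the log2 ratio was 0.80 with no background subtraction, 2.82 with plain subtraction, 0.27 with median centring, -0.045 with mean foreground and 2.63 in the deposited ratios. At 36 h it was -0.69 with no background subtraction, -0.53 with plain subtraction, -0.28 with mean foreground and -0.35 in the deposited ratios.

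Median centring moved the median of all measured genes to -0.11 at 24 h and to 0.15 in Wip1 KO over time, from 0.01 and 0.05, and directions under it are relative to these shifts. The deposited ratios were not run for the time courses, which they cannot give, and the stricter filter gives no value for Ppm1d. No paired analysis was possible because each time has 1 array, and no replicate could be left out. Signal over background limits what could be seen: 2745 gene probes at 24 h and 2021 at 36 h were above background in WT only, against 129 and 187 in Wip1 KO only. The background SD was larger in the Cy5 channel (53.6 against 39.1 at 24 h), and of 1886 genes above background in WT only at 24 h, 621 had a bound under 1-fold and 8 reached 2-fold, so this excess is not read as lower expression.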

Other observations

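All values and tests here were chosen only after the result was seen. Beyond the lists, genes of several further functions stood at least 2-fold apart at both times. The differentiation inhibitor Id1 was higher in Wip1 KO at 24 h (log2 ratio 1.54) and lower at 36 h (-1.78), as were the galectin gene Lgals1 (1.31 and -1.12) and the lactate transporter gene Slc16a3 (1.28 and -1.16). Higher at both times were the carbonic anhydrase gene Car3 (1.10 and 1.03), the chaperone gene Clu (1.08 and 1.02), the methyltransferase gene Inmt (1.31 and 1.02), the uridine phosphorylase gene Upp2 (1.33 and 1.95) and the reticulophagy receptor gene Retreg1 (1.60 and 1.14). The interferon-inducible genes Ly6a (-1.25 and -1.27) and Irgm2 (-1.62 and -1.05), which are in no list, and the lipid transfer gene Pctp (-1.29 and -1.88) were lower at both times. Cyp2e1, of the drug metabolism list and made around the central vein like Glul, had log2 ratios of 0.40 at 24 h and 1.56 at 36 h.

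Genes above background in 1 channel only extend the 36 h comparison. In Wip1 KO only, 10 of 119 such genes were at least 2-fold higher, led by Serpina4-ps1 (at least 5.48-fold). In WT only, 73 of 1478 were at least 2-fold lower in Wip1 KO, among them the female-biased genes Hao2 (at least 8.13-fold) and Cyp2b13 (6.43-fold), the bile duct marker Prom1 (6.02-fold) and the chemokine gene Cxcl3 (5.32-fold). At 24 h the bounds were at least 2-fold for 10 of 88 genes in Wip1 KO only, such as Sugct (at least 5.63-fold) and Slc15a2 (3.24-fold), and for 8 of 1886 in WT only, such as Sult3a1 (12.1-fold) and Cyp7a1.

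Some spots moved alike in both genotypes between the arrays. Sap30l was above background at 36 h only, at least 22.7-fold higher in WT and 16.6-fold in Wip1 KO, as were Itgb1 (20.2-fold and 28.0-fold) and Edn3 (7.21-fold and 10.8-fold). Mrpl47 was above background at 24 h only, at least 9.51-fold lower at 36 h in WT and 6.90-fold in Wip1 KO. A spot that differs between arrays and a change with time give the same values here.

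Probes without a gene name carried differences as well. Of 1429 unnamed probes measured at 24 h, 40 were at least 2-fold higher and 15 at least 2-fold lower in Wip1 KO, and of 1293 at 36 h, 22 and 29.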
